A study of Mus with 15 samples.

How the data were processed

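RNA sequencing was done on adipose tissue of wild-type C57BL/6 mice in 3 groups of 5 samples, which are control tissue, fat grafts at day 3 and fat grafts at day 7, per the labels. RNA was extracted with Trizol and RNeasy columns and sequenced as stranded mRNA libraries with paired reads of 151 bp, per the labels' protocols. The submitters' processing notes name cutadapt 2.8, STAR 2.7.1a, RSEM 1.3.1 and the mouse build mm10, without the role of each tool. The annotation release is not given in the sources used here, and the labels do not say whether replicates came from separate animals, so the tests measure the spread between these samples.

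The authors deposited a matrix of 55471 genes with 45 value columns, which are an estimated count, an RPKM and a TPM for each of 15 samples. The estimated counts deposited by the authors are whole numbers per gene with no scaling, per the file headers and the values. The deposited RPKM values are scaled by the authors for gene length and library size, and they were not used in any test. The deposited TPM values, made by the authors to sum to the same total in each sample, served only in an alternative fit. All 45 value columns were mapped to samples through their sample numbers. Gene symbols, Ensembl identifiers and positions were taken from the matrix, where 118 symbols were repeated, and the entry with the most counts was used for a listed gene.

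Total estimated counts ranged from 17.1 to 32 M per sample. Genes entered the tests with a CPM of at least 0.3894, which is 10 counts at the median library size, in at least 5 samples and at least 15 counts in all, which left 16051 genes. Library sizes were scaled by trimmed means of M-values, with trims of 30% on log ratios and 5% on abundance, and the factors ranged from 0.746 to 1.14. The estimated counts, with no pseudocount of their own, were passed to voom in limma 3.58.1 under R 4.3.3, with the 15 samples in 1 fit of 3 group means. Voom adds a small offset before taking logs, so the size of a change depends on it where counts are at or near 0. Adjusted p-values are those of limma's moderated test with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. Fitted log2 fold changes compare means of log values, so 1 high control makes a ratio of mean CPM smaller than the fitted change. CPM values use the scaled library size, and scores of gene lists are means of log2(CPM + 1).

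A quasi-likelihood test of the counts was planned before the data were examined. It was not run, because the count columns, written with digit separators, were handled as a unit other than plain counts, and limma-voom, also planned, took its place. The same holds for the planned Wald test. The 41 gene lists, with 495 members that were all found in the matrix, were also fixed before the data were examined. A list was tested where at least 3 members passed the filter, which held for 39 lists. The keratinocyte list (2 of 8 members tested) and the epididymis list (1 of 7) were not tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of the comparison. The correlation estimated from the data and limma's fry served as alternatives. Counts adjusted over the list alone use the p-values of the list's members only.

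Genes were named by a rule fixed before the data were examined. It took the 4 highest and the 4 lowest log2 fold changes of each comparison among called genes with a mean of at least 10 CPM in 1 group, no overlap of samples between the groups, and a symbol that is not a predicted gene, a pseudogene or an immunoglobulin or T cell receptor segment. It added in each of 10 lists the 2 called members with the largest changes and at least 10 CPM, and a fixed panel of Hif1a, Slc2a1, Slc2a4, Hk2, Ldha, Adipoq, Pparg and Adgre1. In any list up to 2 members of the majority direction and up to 3 of the other direction could be named as examples. The results of some single genes are not reported here.

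Alternatives fixed then changed the scaling (median of ratios, upper quartile or library totals), the filter on low counts, the samples in the fit, a replicate block and the most abundant genes, and left out each sample in turn. Alternatives added after seeing the data used sample quality weights, limma-trend on log2(CPM + 1) or on log2(TPM + 1), or left out the libraries that stood apart. The fit was tested on simulated counts with a dispersion of 0.1 and 200 changed genes. It recovered 1.49%, 29.9% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold in the layout of day 3 against control (16227 genes), with 3 false calls. For day 7 against control (16229 genes) the shares were 2.99%, 22.4% and 97.0%, with 6 false calls, and for day 7 against day 3 (16236 genes) 0%, 22.4% and 97.0%, with 1 false call. The matrix was read with the R package data.table (1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.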

Results

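Gene expression was measured by RNA sequencing in mouse adipose tissue in 3 groups of 5 samples, which were control tissue, fat grafts at day 3 and fat grafts at day 7. Total estimated counts were 17.1 to 31.8 M in the controls (21.6 ± 5.83 M, mean ± SD) and 23.7 to 29.4 M in the day 3 grafts (26.2 ± 2.14 M). They were 20.2 to 32 M in the day 7 grafts (26.8 ± 4.35 M). Transcripts of the mitochondrial genome took 11.8 ± 2.59% of the counts in the controls, 3.11 ± 0.751% at day 3 and 2.49 ± 0.354% at day 7. The first principal component (62.1% of the variance) separated controls from grafts and the second (11%) separated most day 3 from most day 7 grafts. Day 3 graft 1 and day 7 graft 5 lay between the graft groups on the second component, at 6.62 and -11.9. Levels below are mean CPM ± SD and changes are log2 fold changes ± SE, each with n = 5 per group and adjusted p-values from limma.

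**Figure D1:**
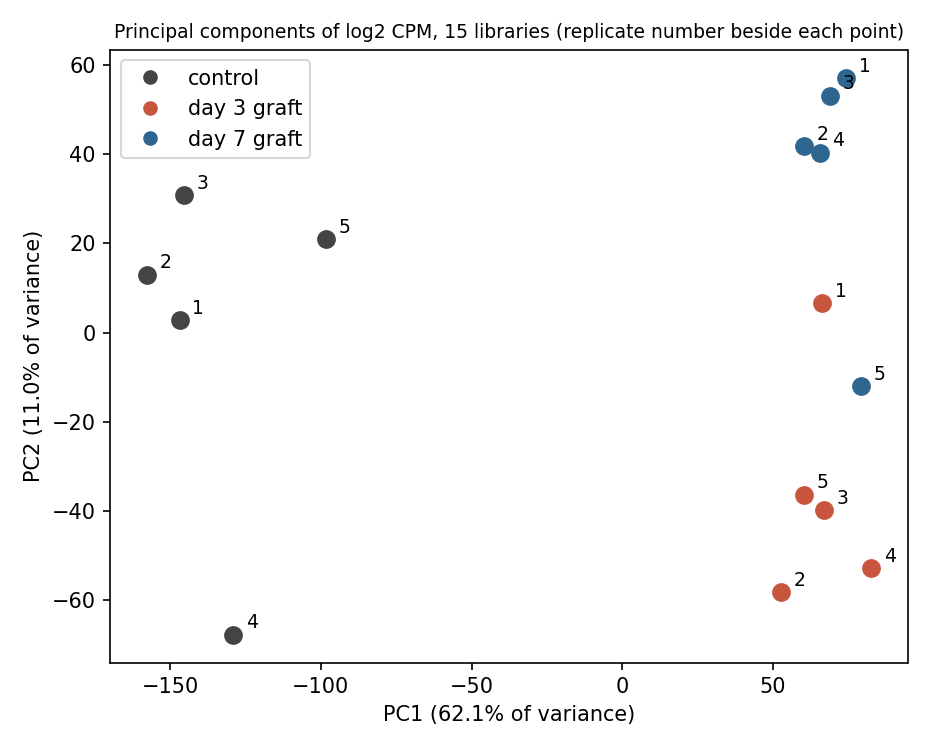
Positions of the 15 libraries (1 point each, coloured by group) on the first and second principal components of voom's log2 CPM, in arbitrary units. The axes hold 62.1% and 11% of the variance. Day 3 graft 1 (6.62) and day 7 graft 5 (-11.9) lie between the other day 3 and day 7 grafts on the second component.

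The comparison of day 3 grafts with controls addressed how the expression of glycolytic and other genes differed early after grafting, since the series concerns a turn of grafted fat toward glycolysis. Of 19 glycolysis enzymes 12 rose, 3 fell and 4 did not pass (13 and 3 adjusted over the list alone), with a median log2 change of 1.07 (camera adjusted p = 0.00712, adjusted p = 0.419 with an estimated correlation). Hk3, a hexokinase of myeloid cells, rose from 7.38 ± 3.85 to 91.2 ± 26.5 CPM (3.68 ± 0.28, adjusted p = 2.22e-07). The aldolase Aldoc rose by 2.45 ± 0.32 (adjusted p = 1.66e-05). The 3 that fell were Ldhb, the lactate dehydrogenase subunit of oxidative tissues (-3.86 ± 0.31, adjusted p = 3.58e-07), Eno3, the muscle enolase (-1.73 ± 0.54, adjusted p = 0.0125), and Pfkm (-1.27 ± 0.37, adjusted p = 0.00908). Skeletal muscle markers had a score, the mean log2 expression of the list in a library, of 8.23 in control 2, 1.83 to 4.96 in the other controls, 4.60 in day 3 graft 1 and 0.422 to 0.727 in the other day 3 grafts. Without control 2 Eno3 was at -1.30 and Pfkm at -0.88. Ldha, the lactate dehydrogenase subunit of glycolytic tissues, was at 1192 ± 398 CPM in controls and 1736 ± 275 at day 3, with overlapping samples (0.59 ± 0.25, adjusted p = 0.0498). That call ended with median-of-ratios (adjusted p = 0.0553) or upper-quartile scaling (adjusted p = 0.0755), with a filter at 1 CPM (adjusted p = 0.058) and with limma-trend (adjusted p = 0.0528). It also ended without control 1, 2, 3 or 5 (adjusted p = 0.0772, 0.0692, 0.123 and 0.0876), day 3 graft 2, 3, 4 or 5 (0.0606, 0.0957, 0.109 and 0.0599) or day 7 graft 1, 3 or 4 (0.0551, 0.0568 and 0.0548). Hk2, the insulin-responsive hexokinase, was at 110 ± 55.9 and 112 ± 24.7 CPM (0.18 ± 0.40, adjusted p = 0.718), and its change was -0.10 without control 3 and -0.15 with quality weights. The macrophage markers, which rose at a median of 2.26, and the adipocyte markers, which fell at a median of -2.51, moved beside this list.

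Transporters of glucose and lactate and regulators of glycolysis went both ways at day 3, with 5 of 13 higher, 6 lower and 2 not called, the same adjusted over the list alone (median -0.44, camera adjusted p = 0.49, fry adjusted p = 0.0199). Slc2a1, the basal glucose transporter, rose from 18.6 ± 5.41 to 213 ± 85.5 CPM (3.48 ± 0.45, adjusted p = 1.54e-05). Slc2a4, the insulin-responsive glucose transporter of adipocytes and muscle, fell from 218 ± 84.5 to 7.35 ± 3.76 CPM (-4.92 ± 0.38, adjusted p = 2.82e-07). Slc16a3, a lactate exporter, rose from 3.39 ± 2.59 to 230 ± 59.4 CPM (6.34 ± 0.56, adjusted p = 6.71e-07) and the pyruvate dehydrogenase kinase Pdk3 rose by 1.38 ± 0.23 (adjusted p = 0.000144). Pfkfb1, an enzyme that sets the activity of phosphofructokinase, had a change of -2.87 ± 0.31 (adjusted p = 3.08e-06). Hif1a, the oxygen-regulated transcription factor subunit, rose from 99.1 ± 30.1 to 253 ± 67.9 CPM (1.35 ± 0.23, adjusted p = 0.000175). Of 17 other genes of the hypoxia response 14 rose and none fell (14 and 0 adjusted over the list alone), with a median of 3.07 (camera adjusted p = 9.02e-06, adjusted p = 0.292 with an estimated correlation). They included the collagen cross-linking enzyme Lox (72.3 ± 68.2 to 1149 ± 351 CPM, 4.46 ± 0.58, adjusted p = 1.65e-05) and the HIF prolyl hydroxylase Egln3 (4.15 ± 0.69, adjusted p = 0.000136).

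On the build mm10, with identifiers and positions as the matrix gives them, the panel held Hif1a (ENSMUSG00000021109, chromosome 12, 73901375 to 73947530), Slc2a1 (ENSMUSG00000028645, chromosome 4, 119108711 to 119137983), Slc2a4 (ENSMUSG00000018566, chromosome 11, 69942539 to 69948188) and Hk2 (ENSMUSG00000000628, chromosome 6, 82725025 to 82774454). It also held Ldha (ENSMUSG00000063229, chromosome 7, 46841475 to 46855627), Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028), Pparg (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399) and Adgre1 (ENSMUSG00000004730, chromosome 17, 57358691 to 57483527). Among the other genes with large changes were Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), Thrsp (ENSMUSG00000035686, chromosome 7, 97412938 to 97417730) and Cfd (ENSMUSG00000061780, chromosome 10, 79890853 to 79892655).

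**Figure D2:**
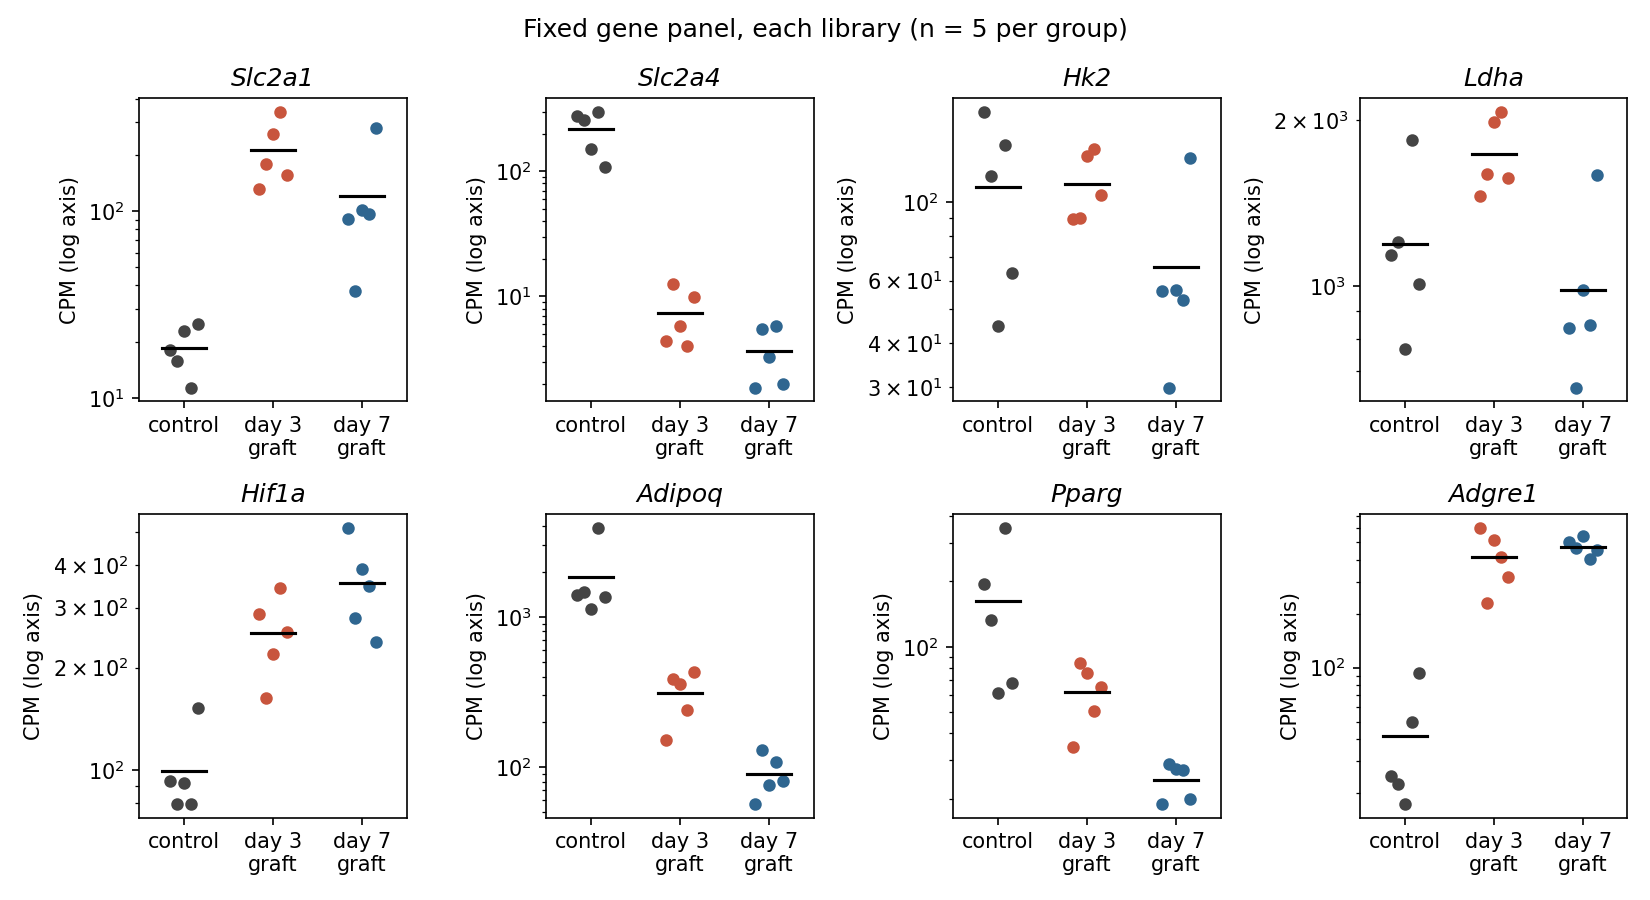
CPM per library (points, logarithmic axis) and group means for the 8 genes of the fixed panel in controls, day 3 grafts and day 7 grafts. Slc2a1 rises from a mean of 18.6 to 213 and 121 CPM while Slc2a4 falls from 218 to 7.35 and 3.68 CPM.

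Genes of adipocytes and of mitochondrial metabolism fell at day 3. All 16 adipocyte markers fell (16 adjusted over the list alone), with a median of -2.51 (camera adjusted p = 8.72e-07, adjusted p = 0.286 with an estimated correlation). Adipoq, which encodes the hormone adiponectin, went from 1850.5 ± 1156 to 313 ± 116 CPM (-2.49 ± 0.37, adjusted p = 4.91e-05). The adrenergic receptor Adrb3 changed by -4.49 ± 0.64 (adjusted p = 3.30e-05). Pparg, the master regulator of fat cell formation, went from 162 ± 119 to 62.0 ± 19.8 CPM (-1.14 ± 0.39, adjusted p = 0.021). That call ended without control 1 (-0.99, adjusted p = 0.057), control 4 (-0.77, adjusted p = 0.05) or day 3 graft 1 (-0.94, adjusted p = 0.0598). All 14 genes of fatty acid and triglyceride synthesis fell, at a median of -4.18 (camera adjusted p = 3.87e-11, adjusted p = 0.286 with an estimated correlation). Thrsp, a regulator of lipid synthesis, went from 1522 ± 597 to 3.29 ± 1.47 CPM (-8.84 ± 0.35, adjusted p = 2.33e-09). The fatty acid synthase Fasn went from 7904 ± 3555 to 56.6 ± 14 CPM (-6.98 ± 0.34, adjusted p = 1.11e-08). All 11 genes of lipolysis and the lipid droplet fell (median -2.28, camera adjusted p = 0.000171, adjusted p = 0.3 with an estimated correlation).

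The mitochondrial lists fell along with the mitochondrial share of counts. All 21 genes of pyruvate dehydrogenase and the TCA cycle fell (median -1.75, camera adjusted p = 8.50e-12, adjusted p = 0.286 with an estimated correlation). Among them were the pyruvate carboxylase Pcx (-4.91 ± 0.34, adjusted p = 1.40e-07) and the dehydrogenase subunit Pdhb (-2.88 ± 0.19, adjusted p = 1.08e-07). Of 39 nuclear genes of the respiratory chain 38 fell (median -1.17, camera adjusted p = 1.48e-12, adjusted p = 0.292 with an estimated correlation). Examples were Cyc1, a cytochrome of complex III (234 ± 78.1 to 58.5 ± 3.12 CPM), and Ndufv1 of complex I (186 ± 55.7 to 48.6 ± 3.07 CPM). The 13 respiratory chain genes of the mitochondrial genome, whose counts are uncertain because nuclear copies took 2.90% of control counts and 0.851% at day 3, all fell (median -1.97, camera adjusted p = 5.43e-07, adjusted p = 0.286 with an estimated correlation). In fatty acid oxidation 19 of 20 fell (median -2.09, camera adjusted p = 1.96e-08, adjusted p = 0.286 with an estimated correlation). Among them were Acsl1, which activates fatty acids (2224 ± 850.1 to 150 ± 58.4 CPM, -3.90 ± 0.31), and Cpt1b, the muscle carnitine palmitoyltransferase (-3.40 ± 0.48). Cpt1a, the form of that enzyme in liver and many other cells, rose from 63.4 ± 18.4 to 202 ± 28.6 CPM (1.71 ± 0.18, adjusted p = 2.33e-06). For each list of lipid and mitochondrial genes at day 3 the counts adjusted over the list alone were the same.

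Genes of inflammation, macrophages and tissue remodelling rose at day 3. All 12 macrophage markers rose (12 adjusted over the list alone), at a median of 2.26 (camera adjusted p = 5.52e-06, adjusted p = 0.286 with an estimated correlation). They included Adgre1, a macrophage surface receptor (41.6 ± 31.7 to 415 ± 148 CPM, 3.52 ± 0.40, adjusted p = 4.55e-06), the Fc receptor Fcgr1 (4.52 ± 0.42) and the integrin Itgam (4.22 ± 0.46). Of 9 markers of lipid-associated macrophages 7 rose (7 adjusted over the list alone), at a median of 3.20 (camera adjusted p = 0.000333, adjusted p = 0.286 with an estimated correlation). The highest included Spp1, osteopontin (22.1 ± 42.2 to 1672 ± 722 CPM), and the metalloelastase Mmp12 (2.44 ± 1.77 to 288 ± 86.3 CPM). Of 15 cytokine genes 13 rose (13 adjusted over the list alone), at a median of 4.61 (camera adjusted p = 2.76e-05, adjusted p = 0.286 with an estimated correlation). They included the chemokines Cxcl2 (7.59 ± 1.48) and Ccl7 (6.27 ± 0.50). All 19 genes of the extracellular matrix and its remodelling rose (19 adjusted over the list alone), at a median of 3.04 (camera adjusted p = 1.44e-08, adjusted p = 0.286 with an estimated correlation). They included the protease inhibitor Timp1 (6.63 ± 0.77) and the matrix glycoprotein Thbs1 (4.61 ± 0.60). Of 14 endothelial markers 7 rose (7 adjusted over the list alone), such as Emcn (1.86 ± 0.30) and the transcription factor Erg (1.78 ± 0.34), with a list median of 0.70 (camera adjusted p = 0.0438, adjusted p = 0.616 with an estimated correlation). That list call ended without day 3 graft 2 (0.43, adjusted p = 0.102) or control 1, 3 or 5 (adjusted p = 0.0554, 0.0601 and 0.0679), with library totals (0.0537), with a filter at 1 CPM (0.0545) and on TPM (0.0695). Control 5, with the highest cytokine score of the controls (2.90 against 1.25 to 1.73), moved several values, and without it the changes were 9.25 for Spp1, 8.29 for Cxcl2, 7.00 for Ccl7, 7.68 for Timp1 and 5.26 for Thbs1.

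The largest rises at day 3 with no overlap of samples were led by Arg1, arginase 1 (2.12 ± 3.16 to 1273 ± 886 CPM, 10.21 ± 1.28, adjusted p = 1.13e-05). Next came Serpinb2, a plasminogen activator inhibitor (9.45 ± 2.00, adjusted p = 0.000954), and Cxcl5, a chemokine for neutrophils (8.56 ± 1.96, adjusted p = 0.00169). Their size moved with single controls, to 9.43 and 8.41 for Arg1 and Serpinb2 without control 3, to 11.01, 11.28 and 10.19 for the 3 genes without control 5, and to 7.88 and 7.95 for Cxcl5 without control 1 or 2. The largest falls were those of Glycam1, a ligand for L-selectin on lymph node venules (104 ± 57.8 to 0.0996 ± 0.223 CPM, -10.73 ± 3.03, adjusted p = 0.00684), and of Cr2, a complement receptor of B cells (142 ± 85.3 to 0.153 ± 0.0759 CPM, -9.38 ± 1.56, adjusted p = 0.000132). Others were those of Ccl21a, a chemokine of lymphoid tissue (240 ± 166 to 0.616 ± 0.817 CPM, -9.12 ± 3.22, adjusted p = 0.0236), and Thrsp. Without control 4 the changes were -11.72 for Glycam1, -10 for Cr2 and -10.48 for Ccl21a, and without day 3 graft 2 that of Glycam1 was -11.67. Glycam1 was at 0 CPM in day 3 grafts 1, 3, 4 and 5, and Ccl21a was at 0 in day 3 graft 4. The size and rank of these falls thus depend on voom's offset and are not measured folds. The call of Ccl21a ended without day 3 graft 2 (-9.95, adjusted p = 0.0607) or day 3 graft 5 (-9.77, adjusted p = 0.0576), and its change was -8.23 without day 3 graft 4. All 9 B cell markers fell (9 adjusted over the list alone), at a median of -6.99 (camera adjusted p = 2.50e-05, adjusted p = 0.286 with an estimated correlation). They included Ms4a1, a B cell surface protein (196 ± 105 to 0.685 ± 0.499 CPM). Of 15 T and NK cell markers 10 fell (10 adjusted over the list alone), at a median of -4.57 (camera adjusted p = 0.0106, adjusted p = 0.534 with an estimated correlation). They included Cd8a (-6.81 ± 2.07, and -7.90 without control 4). Without control 4 the list medians were -7.61 for B cells and -5.38 for T and NK cells. Control 4 stood apart in these lymphocyte genes, with a median of 2.97 CPM over 8 genes of lymph node structure against 98.2 to 147 in the other controls and 0.0540 to 0.525 in the grafts. Of these genes Cxcl13 was higher in day 3 graft 1 (46.43 CPM) and day 7 graft 5 (124.2 CPM) than in control 4 (33.35 CPM).

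**Figure D3:**
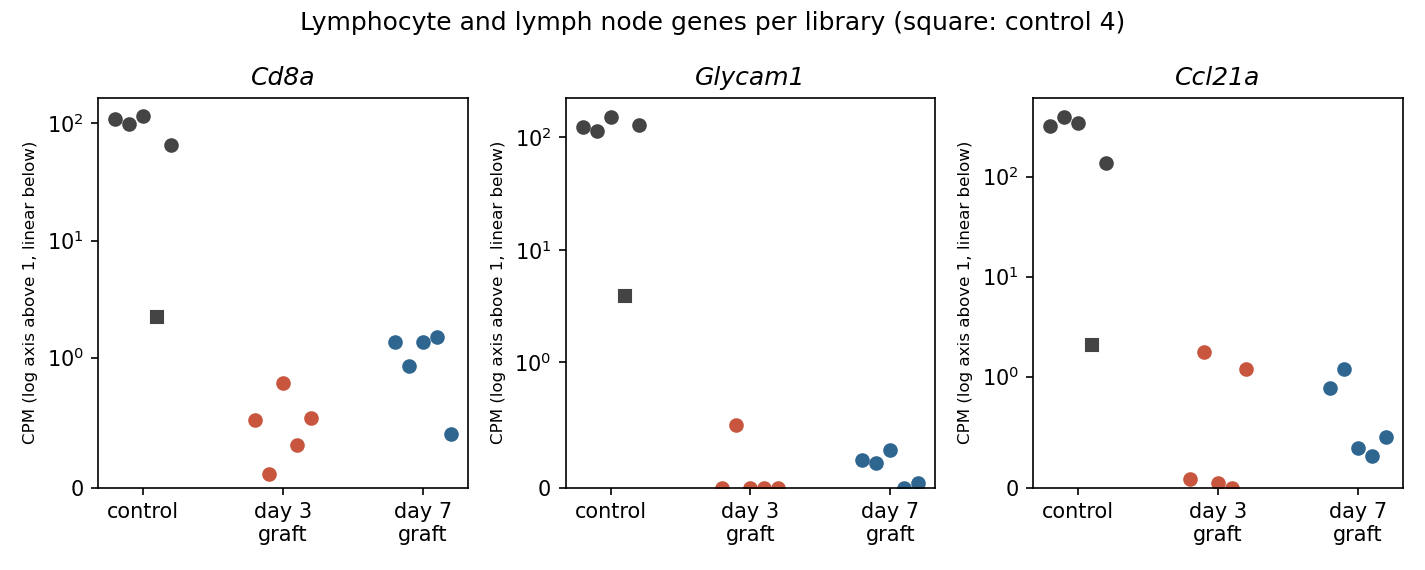
CPM per library (points, logarithmic axis that is linear at the lowest values) of Cd8a, Glycam1 and Ccl21a in controls, day 3 grafts and day 7 grafts. Control 4 lies far below the other 4 controls, and all 10 grafts lie low.

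Over all genes, 4838 were higher and 4846 lower at day 3 than in the controls, which is 60.3% of the 16051 tested, and 2704 and 2745 of them changed at least 2-fold. On the deposited TPM 68.0% of 9268 called genes were higher, beside a shift of the median of all genes of 0.284. With changes in most genes, each value is relative to the scaling, which sets the bulk of genes near 0, and no camera call of any comparison held with an estimated correlation.

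The comparison of day 7 grafts with controls addressed the same question later after grafting. Of 19 glycolysis enzymes 8 rose, 4 fell and 7 did not pass (8 and 4 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.292, adjusted p = 0.705 with an estimated correlation). Hk3 rose to 64.9 ± 6.10 CPM (3.24 ± 0.28, adjusted p = 3.87e-07) and Aldoc rose by 2.04 ± 0.33 (adjusted p = 9.52e-05). Ldhb (-3.45 ± 0.29, adjusted p = 3.41e-07), Aldoa, the main aldolase (-0.95 ± 0.28, adjusted p = 0.00874), and Eno3 (-1.51 ± 0.52, adjusted p = 0.021) fell. The call of Eno3 ended without day 7 graft 2 (adjusted p = 0.0531), and its change was -1.09 without control 2. Ldha was at 984 ± 360 CPM (-0.28 ± 0.24, adjusted p = 0.319, and -0.38 with adjusted p = 0.0322 under quality weights and 0.12 with adjusted p = 0.555 on TPM). Hk2 was at 65.7 ± 39.2 CPM (-0.74 ± 0.39, adjusted p = 0.115), and it passed without day 7 graft 5 (-1.06, adjusted p = 0.0193) or control 3 (-1.01, adjusted p = 0.0288) and with quality weights (-1.31, adjusted p = 0.000836). Of the 13 transporters and regulators 4 rose and 6 fell, the same adjusted over the list alone (median -0.45, camera adjusted p = 0.18, fry adjusted p = 0.000537). Slc2a1 rose to 121 ± 91.7 CPM (2.46 ± 0.44, adjusted p = 0.000228) and Slc16a3 to 126.5 ± 68.1 CPM (5.33 ± 0.56, adjusted p = 2.11e-06). Slc2a4 fell to 3.68 ± 1.87 CPM (-5.95 ± 0.44, adjusted p = 1.58e-07). Hif1a rose to 353 ± 107 CPM (1.83 ± 0.24, adjusted p = 1.46e-05). Of 17 other genes of the hypoxia response 12 rose and 1 fell (12 and 1 adjusted over the list alone), at a median of 2.09 (camera adjusted p = 0.00152, adjusted p = 0.442 with an estimated correlation). Lox (4.25 ± 0.58) and the collagen hydroxylase Plod2 (4.04 ± 0.27) rose, and Vegfa, the main growth factor for vessels, fell from 253 ± 142 to 107 ± 70.1 CPM (-1.29 ± 0.42, adjusted p = 0.0165).

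Adipocyte and mitochondrial genes were low at day 7. All 16 adipocyte markers fell, at a median of -4.30 (camera adjusted p = 7.86e-10, adjusted p = 0.258 with an estimated correlation). Adipoq was at 90.1 ± 28.5 CPM (-4.24 ± 0.35, adjusted p = 3.21e-07) and Pparg at 24.4 ± 4.64 CPM (-2.44 ± 0.41, adjusted p = 0.000128). Cfd, the complement factor adipsin, went from 8055 ± 4480 to 109 ± 32.5 CPM (-6.13 ± 0.36, adjusted p = 3.17e-08) and Adrb3 was at -7.16 ± 0.96. All 14 genes of fatty acid and triglyceride synthesis fell (median -4.93, camera adjusted p = 2.91e-12, adjusted p = 0.258 with an estimated correlation). All 11 of lipolysis and the lipid droplet also fell (median -4.14, camera adjusted p = 7.12e-07, adjusted p = 0.258 with an estimated correlation). All 21 genes of pyruvate dehydrogenase and the TCA cycle (median -1.77, camera adjusted p = 1.10e-12, adjusted p = 0.258 with an estimated correlation) fell. So did all 39 nuclear genes of the respiratory chain (median -1.26, camera adjusted p = 1.48e-14, adjusted p = 0.280 with an estimated correlation). Pcx was at -6.16 ± 0.36 and Uqcrfs1, the Rieske protein of complex III, at -1.99 ± 0.17. The 13 genes of the mitochondrial genome, uncertain as at day 3, fell at a median of -2.34 (camera adjusted p = 3.49e-08, adjusted p = 0.258 with an estimated correlation). In fatty acid oxidation 19 of 20 fell (median -2.32, camera adjusted p = 7.96e-10, adjusted p = 0.258 with an estimated correlation). Acsl1 was at -4.90 ± 0.30 and Eci1, an enoyl-CoA isomerase, at -3.15 ± 0.26, and Cpt1a rose by 1.72 ± 0.18. The counts of these 7 lists were the same adjusted over the list alone.

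Macrophage and matrix genes were high at day 7. All 12 macrophage markers rose (12 adjusted over the list alone), at a median of 2.61 (camera adjusted p = 4.67e-06, adjusted p = 0.280 with an estimated correlation). Adgre1 was at 472 ± 53.1 CPM (3.77 ± 0.40, adjusted p = 2.52e-06) and Itgam at 571 ± 186 CPM (3.49 ± 0.44). Of 9 lipid-associated macrophage markers 8 rose (8 adjusted over the list alone), at a median of 4.96 (camera adjusted p = 5.33e-05, adjusted p = 0.258 with an estimated correlation). Spp1 was at 2627 ± 149 CPM (8.94 ± 0.80) and Mmp12 at 585 ± 177 CPM (8.07 ± 0.42). All 19 matrix genes rose (19 adjusted over the list alone), at a median of 3.60 (camera adjusted p = 2.34e-09, adjusted p = 0.258 with an estimated correlation). The glycoprotein tenascin C, Tnc, went from 36.7 ± 49.8 to 1307 ± 313 CPM (5.86 ± 0.57, adjusted p = 1.11e-06) and Timp1 was at 5.92 ± 0.76. All 17 proliferation genes rose (17 adjusted over the list alone), at a median of 1.96 (camera adjusted p = 5.72e-05, adjusted p = 0.442 with an estimated correlation). The mitotic kinase Cdk1 went from 12 ± 6.32 to 77.0 ± 19.8 CPM. Of 12 called cytokine genes, out of 15, none fell (12 adjusted over the list alone, median 3.8, camera adjusted p = 0.000488, adjusted p = 0.280 with an estimated correlation). The endothelial markers had 9 of 14 higher, such as the cadherin Cdh5 (1.66 ± 0.28) and Erg (1.39 ± 0.35), 9 also adjusted over the list alone, while the list did not pass (median 0.90, camera adjusted p = 0.0514, adjusted p = 0.631 with an estimated correlation). It passed without control 4 (0.97, adjusted p = 0.0273), day 7 graft 2 or 5 (1.01 and 0.97, adjusted p = 0.0304 and 0.0224) or any 1 of the 5 day 3 grafts (adjusted p = 0.0172, 0.0184, 0.0444, 0.0434 and 0.0447). It also passed by fry (adjusted p = 0.0338), with median-of-ratios (0.0438) or upper-quartile scaling (0.0481), with no filter (0.00409) and without the 50 most abundant genes (0.0446). The same held with quality weights (adjusted p = 0.011) and with only the 10 samples compared (0.00918). Without control 5 the changes were 10 for Spp1, 6.97 for Timp1 and 6.5 for Tnc.

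The largest rises at day 7 were those of Arg1 (9.32 ± 1.27, adjusted p = 2.11e-05), Lrrc15, a membrane protein of activated fibroblasts (2.13 ± 4.03 to 325 ± 96.5 CPM, 8.96 ± 0.88, adjusted p = 1.29e-06), and Spp1. The largest falls at day 7 were those of Cidea, a lipid droplet protein (206 ± 96.7 to 0.298 ± 0.294 CPM, -9.61 ± 0.86, adjusted p = 5.38e-07), and of Thrsp (-9.07 ± 0.36, adjusted p = 2.24e-09). Glycam1 (-9 ± 2.55, adjusted p = 0.00696) and Cox8b, a respiratory chain subunit of muscle and brown fat (-8.88 ± 1.12, adjusted p = 1.13e-05), followed. Glycam1 was at 0 to 0.3 CPM in the day 7 grafts, so the size of its fall depends on voom's offset here too. Arg1 stood at 8.54 without control 3 and 10.12 without control 5, Lrrc15 at 9.95 and Spp1 at 10 without control 5, and Glycam1 at -10 without control 4. All 9 B cell markers fell (9 adjusted over the list alone), at a median of -6.5 (camera adjusted p = 1.99e-05, adjusted p = 0.280 with an estimated correlation). Of 15 T and NK cell markers 9 fell (10 adjusted over the list alone), at a median of -3.81 (camera adjusted p = 0.0298, adjusted p = 0.623 with an estimated correlation). That list call ended without day 7 graft 5 (adjusted p = 0.0863) or that library and day 3 graft 1 (0.0849), with a filter at 1 CPM (0.0645) and with only the 10 samples compared (0.0631). Without control 4, which is the same library as in the comparison at day 3, the list medians were -7.10 for B cells and -4.63 for T and NK cells. Over all genes 5177 were higher and 4559 lower than in the controls, 60.7% of those tested, and 2972 and 2553 changed at least 2-fold. On the deposited TPM 74.1% of 9981 called genes were higher, beside a shift of the median of 0.379. The controls were shared by both comparisons. Of the genes called in them 4203 were higher and 3964 lower at both days (1560 and 1376 for independent calls), and 14 went opposite ways. With controls 1 and 2 used for day 3 and the others for day 7, 3150 were higher and 3071 lower at both days (1041.5 and 975 for independent calls), and 10 went opposite ways. With controls 1, 2 and 3 used for day 3, 2979 were higher and 2862 lower (1115 and 1105), and 49 went opposite ways. The changes of the comparisons had a correlation of 0.916 with all controls, and of 0.874 and 0.800 in these divisions. In simulated groups with no change, the shared controls alone gave 0.508. The covariance of the changes was 0.0518 in those groups, at a dispersion of 0.1. It was 2.45 in the data with all controls and 2.46 and 2.205 in the divisions, so little of it followed from the shared controls.

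**Figure D4:**
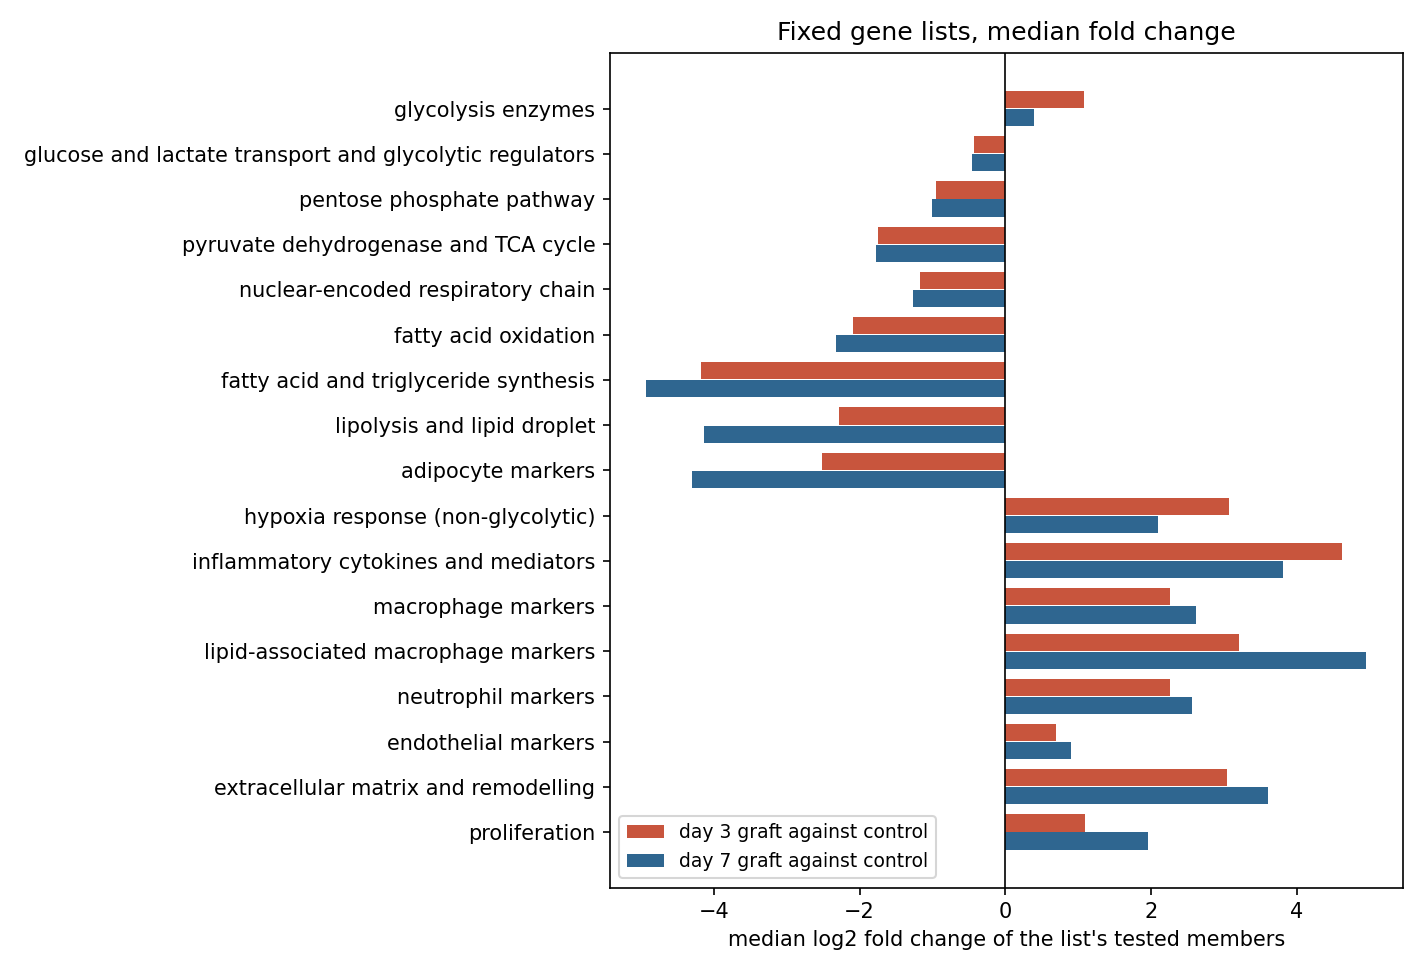
Median log2 fold change (bars) of 17 fixed gene lists for day 3 and day 7 grafts against control. The adipocyte list lies at -2.51 and -4.30 and the glycolysis list at 1.07 and 0.39.

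The comparison of day 7 with day 3 grafts addressed how the grafts changed over time, and whether glycolytic genes stayed at their early level. Of 19 glycolysis enzymes limma called 0 over all genes, 14 were lower and 1 higher at an unadjusted p under 0.05, 11 were lower adjusted over the list alone and limma-trend called 0. The list median was -0.68 (camera adjusted p = 7.38e-06, adjusted p = 0.444 with an estimated correlation, fry adjusted p = 0.0781). Ldha differed by -0.87 ± 0.25 (adjusted p = 0.0571). It passed without day 7 graft 5 (-1.08, adjusted p = 0.00809), control 3 (0.0437) or control 4 (0.0221). It also passed on library totals (0.0246), with no filter (0.0383), without the 50 most abundant genes (0.0474), with the 10 samples alone (0.0319), with quality weights (0.000869) and on TPM (0.0198). Slc2a1 differed by -1.02 ± 0.42 (adjusted p = 0.183) and Hk2 by -0.91 ± 0.40 (adjusted p = 0.209). Both passed without day 7 graft 5, which had the highest level of each among the day 7 grafts (-1.41, adjusted p = 0.0181, and -1.23, adjusted p = 0.0472), and with quality weights (adjusted p = 0.0122 and 0.0153). The transporters and regulators had 0 of 13 called, with 4 lower and 1 higher at an unadjusted p under 0.05, 1 lower adjusted over the list alone and 1 by limma-trend. The list median was -0.56 (camera adjusted p = 0.0163, adjusted p = 0.444 with an estimated correlation, fry adjusted p = 0.0844). The hypoxia response had 0 of 17 called, with 8 lower at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 by limma-trend. The list median was -0.63 (camera adjusted p = 6.10e-05, adjusted p = 0.577 with an estimated correlation, fry adjusted p = 0.245). Hif1a differed by 0.47 ± 0.25 (adjusted p = 0.313) and Slc2a4 by -1.03 ± 0.50 (adjusted p = 0.265).

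Some adipocyte genes fell further between day 3 and day 7. Of 16 adipocyte markers 6 fell (13 adjusted over the list alone), at a median of -1.52 (camera adjusted p = 1.40e-12, adjusted p = 0.441 with an estimated correlation, fry adjusted p = 0.0207). Adipoq went from 313 ± 116 to 90.1 ± 28.5 CPM (-1.75 ± 0.32, adjusted p = 0.00851) and Cfd from 1024 ± 375 to 109 ± 32.5 CPM (-3.19 ± 0.31, adjusted p = 0.000164). Retn, resistin, went from 84.3 ± 34.5 to 18.5 ± 7.22 CPM (-2.16 ± 0.34, adjusted p = 0.00373). Pparg differed by -1.29 ± 0.40 (adjusted p = 0.0773) and passed without control 4 (-1.30, adjusted p = 0.0226), with quality weights (0.00621), on TPM (0.0482) and with the 10 samples alone (0.0122). Of 11 genes of lipolysis and the lipid droplet 7 fell (10 adjusted over the list alone), at a median of -1.89 (camera adjusted p = 6.20e-10, adjusted p = 0.441 with an estimated correlation, fry adjusted p = 0.0207). They included the droplet coat protein Plin1 (145 ± 72.9 to 32.9 ± 14.3 CPM, -2.07 ± 0.43, adjusted p = 0.015). Immediate early and heat shock genes had 6 of 11 lower (10 adjusted over the list alone), at a median of -1.14 (camera adjusted p = 3.28e-09, adjusted p = 0.178 with an estimated correlation, fry adjusted p = 0.00336). Fos went from 217 ± 79.4 to 76.1 ± 22.9 CPM (-1.48 ± 0.30, adjusted p = 0.0124). Interferon response genes had 5 of 11 lower (9 adjusted over the list alone), at a median of -1.30 (camera adjusted p = 3.28e-09, adjusted p = 0.444 with an estimated correlation, fry adjusted p = 0.0365). Irf7, a regulator of interferon genes, went from 369 ± 93.1 to 123 ± 39.3 CPM (-1.62 ± 0.29, adjusted p = 0.00851). Cytokine genes had 4 of 15 lower (6 adjusted over the list alone, 2 by limma-trend), at a median of -0.60 (camera adjusted p = 0.000878, adjusted p = 0.577 with an estimated correlation, fry adjusted p = 0.208). The neutrophil chemokine Cxcl1 was at -2.16 ± 0.45 (adjusted p = 0.0144).

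Some genes of matrix, mural cells and lipid-associated macrophages were higher at day 7 than at day 3. The largest rises were those of Col8a2, a collagen chain (0.198 ± 0.361 to 25.7 ± 14.7 CPM, 8.09 ± 1.43, adjusted p = 0.00752), and of C1qtnf3, a secreted protein of the adiponectin family (7.62 ± 13.8 to 230 ± 142 CPM, 6.59 ± 1.00, adjusted p = 0.00263). Next were the collagen-binding proteoglycan Fmod (0.339 ± 0.0852 to 37.4 ± 20.4 CPM, 6.51 ± 1.14, adjusted p = 0.00701) and Col11a1, another collagen chain (6.12 ± 1.28, adjusted p = 0.0152). Without day 3 graft 1 the changes of Col8a2 and C1qtnf3 were 8.95 and 7.58, and without day 7 graft 5 that of Col11a1 was 6.75. Of 11 pericyte and smooth muscle markers 5 rose (6 adjusted over the list alone), at a median of 1.51 (camera adjusted p = 6.01e-05, adjusted p = 0.444 with an estimated correlation, fry adjusted p = 0.0313). Of 9 lipid-associated macrophage markers 3 rose (3 adjusted over the list alone, 1 by limma-trend), at a median of 0.75 (camera adjusted p = 0.00348, adjusted p = 0.577 with an estimated correlation, fry adjusted p = 0.128). Gpnmb, a glycoprotein of lipid-laden macrophages, went from 125 ± 40.4 to 609 ± 216 CPM (2.26 ± 0.45, adjusted p = 0.0124). Of 12 macrophage markers limma called 0, with 1 higher and 1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 by limma-trend (median 0.22, camera adjusted p = 0.593). Adgre1 differed by 0.25 ± 0.43 (adjusted p = 0.81). Of 19 matrix genes 2 rose (5 adjusted over the list alone, 4 by limma-trend, median 0.51, camera adjusted p = 0.0196, adjusted p = 0.708 with an estimated correlation, fry adjusted p = 0.43). That call of the list ended without day 7 graft 5 (0.36, adjusted p = 0.0539) and without the 50 most abundant genes (0.49, adjusted p = 0.0588). Of 17 proliferation genes 0 were called, with 9 higher at an unadjusted p under 0.05, 7 adjusted over the list alone and 0 by limma-trend. The list median was 0.79 (camera adjusted p = 1.22e-05, adjusted p = 0.577 with an estimated correlation, fry adjusted p = 0.208).

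**Figure D5:**
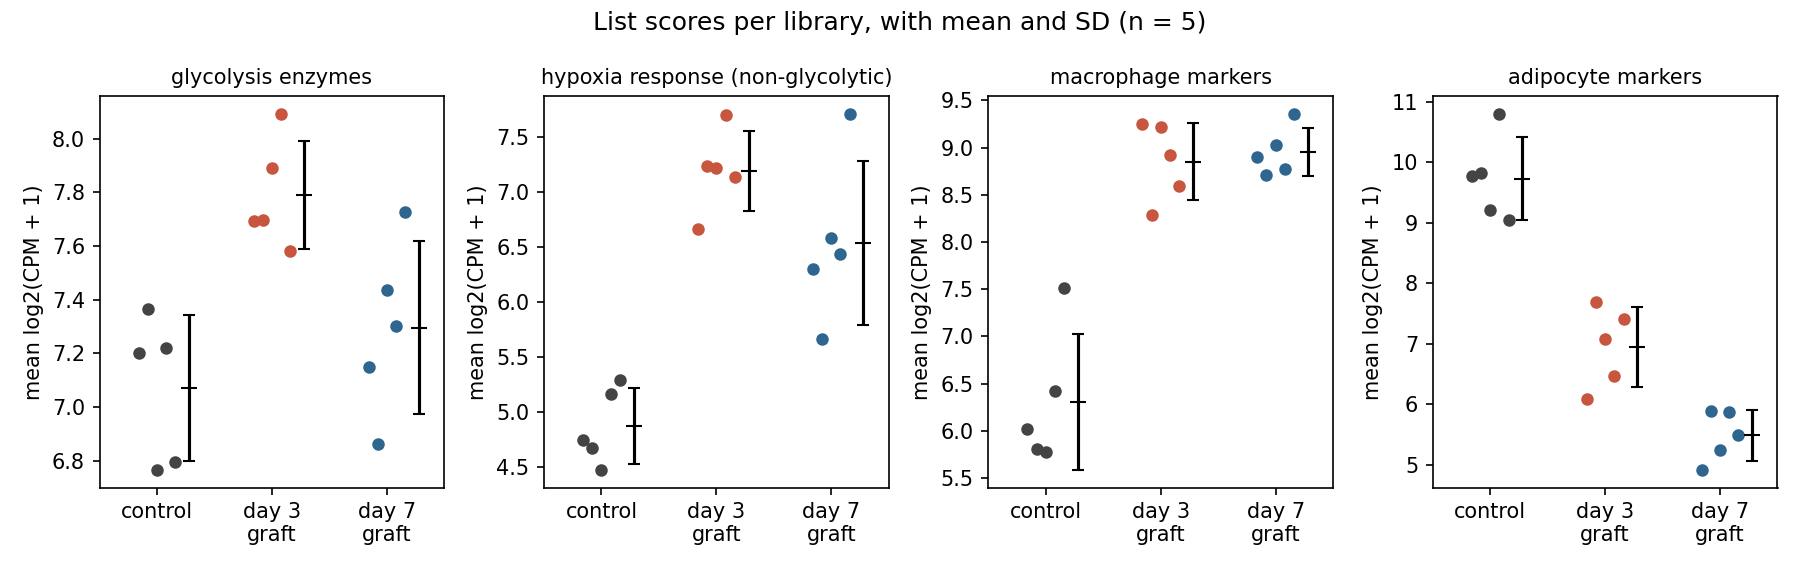
Scores of the glycolysis, hypoxia, macrophage and adipocyte lists per library (points, with mean and SD), as the mean log2(CPM + 1) of the members, in controls, day 3 grafts and day 7 grafts. The glycolysis score goes from 7.79 ± 0.201 at day 3 to 7.30 ± 0.323 at day 7 (mean ± SD, n = 5).

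Other genes with the largest falls from day 3 to day 7 were Orm1, an acute phase protein (35.9 ± 16.3 to 4.96 ± 1.07 CPM, -2.74 ± 0.47, adjusted p = 0.00633), and the tubulin-binding Tppp (-2.58 ± 0.50, adjusted p = 0.0111). Another was Cdsn, an adhesion protein of cornified skin (-3.16 ± 0.77, adjusted p = 0.0322). The call of Cdsn ended without day 3 graft 3, 4 or 5 (adjusted p = 0.0655, 0.0645 and 0.0601) or day 7 graft 1, 2, 3 or 4 (0.0817, 0.0799, 0.0844 and 0.0686). Over all genes 510 were higher and 274 lower at day 7 than at day 3, which is 4.88% of those tested, and 344 and 161 changed at least 2-fold. The total of 784 depended on single libraries, with 1563 without control 4 and 1470 without day 7 graft 5. Control 4 is in neither group of this comparison and acts only through the shared fit, by the pooled spread, the filter and the scaling. A fit on the 10 samples compared, without the controls, called 1400. In the shared fit the total was 348, 349 and 402 without day 3 graft 3, 4 or 5 and 386, 323, 338 and 374 without day 7 graft 1, 2, 3 or 4. Without day 3 graft 1 and day 7 graft 5 it was 1541, which in part follows from leaving out the libraries between the groups.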

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

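In this part the counts of called genes under other splits of the samples and the macrophage test of the fall in glycolysis genes were fixed before their results were seen. The camera, fry and limma-voom tests repeated here were planned, as given above. Every other test was chosen after the result was seen. The glycolysis pattern was divided into a rise and a fall, and the test of mixed RNA and the macrophage test of the rise were added, after the other tests had been run. A library was picked out where it lay far from the other 4 of its group by Dixon's test. This held for 26 of 153 groups of 5, where about 1 in 20 groups, or 7.65, would be picked by chance.

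Most lymphocyte genes were high in 4 controls and low in control 4 and the grafts. The T and NK cell score was 1.82 in control 4 (4.34 to 4.97 in the other controls) and the B cell score 4.95 (7.84 to 8.48). Of the T and NK cell markers, Klrb1c, Ncr1, Gzma and Gzmb did not follow, with ratios of control 4 to the other controls of 0.725, 1.09, 0.723 and 0.5365. Gzma was at 2.495 to 5.061 CPM in the controls, 7.937 to 15.23 in day 7 grafts 1 to 4 and 3.649 in day 7 graft 5. Blood in the control pieces is argued against by the erythroid score of control 4, which was 3.69 log2 units above the lowest of the other controls. Lymph node tissue in some control pieces may account for the difference between the controls, since 8 genes of lymph node structure, in a list written after the result, were at a median of 0.0656 of their level in the other controls. The lowest of the 5 not listed among the largest falls was Chst4 at 0.00908 and the highest Madcam1 at 0.331. Cr2, a receptor of B cells, was at 0.101 and would be low with B cells whether or not a node was present. Cxcl13 did not follow in the grafts, at 46.43 CPM in day 3 graft 1 and 124.2 in day 7 graft 5 against 33.35 in control 4. Fewer lymphocytes in the grafts apart from any lymph node cannot be told apart from lymph node tissue in some controls. The B cell score of control 4 was 2.22 above the highest graft, and the T and NK cell score differed by -0.231 from it, in only 1 such control. Staining of control pieces for lymph nodes would test it.

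Day 7 graft 5 and day 3 graft 1 lay between the graft groups, at 0.403 and 0.392 on an axis from 0 at the day 3 mean to 1 at the day 7 mean of the other 8 grafts. The other day 3 grafts lay at 0.0482 to 0.180 and the other day 7 grafts at 0.867 to 0.973, each scored with itself left out of the axis. A full swap of labels would place each of the 2 libraries in the range of the other group, and neither lay there. Both also lay outside the range of their own group, so these positions do not decide on a swap. RNA of day 3 graft 1 mixed into day 7 graft 5 is argued against by skeletal muscle genes. They summed to 460.5 CPM in day 3 graft 1 and 3.69 CPM in day 7 graft 5, or 0.801%. RNA of day 7 graft 5 mixed into day 3 graft 1 was not tested, since it would carry little muscle RNA. Control fat mixed into day 7 graft 5 is argued against by its adipocyte score, which differed by -2.19 from the highest day 3 graft, and their totals of 25 and 27.8 M lay within the 20.2 to 32 M of the other grafts, which was also looked at. A difference in pace between grafts stays open and was not tested, as were differences between animals or sites of grafting, which the labels do not give.

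The glycolysis list had a median of 1.07 at day 3 against the controls, with 12 of 19 genes higher and 3 lower, and of -0.68 at day 7 against day 3, with 0 called by limma or limma-trend. Both passed by camera and neither with an estimated correlation (adjusted p = 0.419 and 0.444), and by fry the rise passed (adjusted p = 0.000393) and the fall did not (adjusted p = 0.0781). A loss of adipocyte RNA alone, which raises the share of every other cell type, was not decided as a cause of the rise. The Schwann cell markers fell at a median of -1.73, which that loss alone would not give. A separate loss of Schwann cell RNA would also lower them, so they cannot set the part of the rise due to adipocyte loss. Other cell types went both ways. Medians were 0.70 for endothelial, 0.63 for fibroblast, -0.56 for pericyte and smooth muscle and 2.26 for macrophage markers. Macrophage influx may account for the rise and cannot be told apart, since its 2.26 was in the same grafts. For the fall, the glycolysis score minus the macrophage score differed by -0.595 between the days (exact two-sided permutation p = 0.0159, n = 5 per group). The glycolysis score alone differed by -0.496 and the macrophage score alone by 0.0998 (exact permutation p = 0.683 for the latter, n = 5 per group). A fall in step with the macrophage genes is thus argued against. An influx that dilutes other RNA would also lower the difference, so this test does not decide on it. A hypoxia response stronger at day 3 stays open as a cause of the fall, since its score went from 7.19 ± 0.368 to 6.54 ± 0.743 (exact two-sided permutation p = 0.119, n = 5 per group) and the glycolysis score from 7.79 ± 0.201 to 7.30 ± 0.323 (exact two-sided permutation p = 0.0318). The hypoxia score of day 7 graft 5 was 7.71, above all day 3 grafts (6.66 to 7.70), and those of the other day 7 grafts (5.66 to 6.58) were below all of them. Sorted adipocytes, macrophages and endothelial cells from grafts at both days would test which cells carry the change.

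Chance as the source of the called genes was tested on 100 drawn splits of each 10 samples, with a fit on those samples only. Every other split mixes the 2 groups, so a difference between them adds to its spread and lowers its count. Only the rank of the real split is thus informative, and the size of the gap to the others is not. At day 3 only 1 split, the real one, gave at least its 8787 genes, and the highest other gave 1. At day 7 only 1 split gave at least the real 8913, and the highest other gave 11. For day 7 against day 3 only 1 gave at least the real 1400, and the highest other, which exchanges day 3 graft 1 and day 7 graft 5, gave 1174, which points to a structure of the samples.

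Other libraries far from their group were as follows, as list scores in log2 units unless stated. In the controls, control 4 had 6.41 for serine and glutamine metabolism (others 6.29 to 6.32), 5.83 for endothelial markers (5.19 to 5.33) and 4.92 for pericytes (4.59 to 4.68). It also had 3906 CPM of Adipoq (1122 to 1459) and a total of 31.8 M counts (17.1 to 20.3 M). Control 5 had 6.03 for NRF2 targets (5.07 to 5.31), 2.90 for cytokines (1.25 to 1.73), 3.47 for neutrophil markers (1.08 to 1.56) and 151.8 CPM of Hif1a (79.6 to 93.0). Control 1 had 4.38 for keratinocyte markers (0.44 to 1.29). Day 3 graft 1 had 5.07 for glucose and lactate transport and regulators (5.54 to 5.68) and 4.60 for skeletal muscle (0.42 to 0.73), day 3 graft 2 had 2.36 for Schwann cells (1.41 to 1.61) and day 3 graft 3 had 6.74 for fibroblasts (7.59 to 7.79). Day 7 graft 5 had 4.83 for the interferon response (6.00 to 6.44), 7.43 for resident or alternatively activated macrophages (5.15 to 5.51), 2.74 for B cells (1.90 to 2.09), 3.84 for mast cells (2.24 to 2.5) and 4.27 for pericytes (5.53 to 5.96). It further had 5.11 for proliferation (5.87 to 6.07), 2.44 for glandular epithelium (1.07 to 1.39), 1.59 for keratinocytes (0.57 to 0.68), 278 CPM of Slc2a1 (37.5 to 101) and 133 CPM of Hk2 (30.0 to 56.6).

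Effects against the controls that differed between day 7 and day 3 were looked for here among the gene lists and the fixed panel only. By the test of that difference they were the 18 lists called by camera and, of the panel, Adipoq (-1.75, limma adjusted p = 0.00851). None of the 18 passed with an estimated correlation (adjusted p = 0.178 to 0.739), and 13 did not pass by fry. Limma called 0 members of 8 lists, with those at an unadjusted p under 0.05 in brackets: glycolysis (15), transport and regulators (5), nuclear (0) and mitochondrial respiratory chain (1), insulin signalling (1), hypoxia (8), the unfolded protein response (2) and proliferation (9). Limma-trend called 1 member of transport and regulators and 0 of the other 7 lists. Besides glycolysis the 18 lists by camera were, as medians of day 7 minus day 3, transport and regulators (-0.56), nuclear respiratory chain (-0.11), mitochondrial respiratory chain (-0.34), fatty acid oxidation (-0.23), fatty acid and triglyceride synthesis (-0.49) and lipolysis and the lipid droplet (-1.89). They also were adipocyte markers (-1.52), insulin signalling (-0.27), hypoxia (-0.63), the unfolded protein response (-0.21), immediate early genes (-1.14), interferon (-1.30) and cytokines (-0.60). Medians above 0 were those of lipid-associated macrophages (0.75), pericytes and smooth muscle (1.51), the extracellular matrix (0.51) and proliferation (0.79).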

How the results depend on the processing

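Quality weights, limma-trend on CPM or TPM and the fits without the libraries that stood apart were chosen after seeing the data. The planned quasi-likelihood and Wald tests of counts were not run. Of the named genes under each alternative, 2677 results at day 3 kept their side of the threshold and 113 became weaker. At day 7 these were 2710 and 76, and between the days 900 and 140. Where a value below moved, the cause was not tested unless the setting itself has more or fewer genes or samples. With no filter the counts lower by at least 2-fold were 4431 at day 3 and 4284 at day 7, with more genes tested. With quality weights 2128 genes were higher and 1533 lower at day 7 than at day 3, 845 and 498 of them at least 2-fold. On log2(TPM + 1) 2967 genes were lower at day 3 (1362 at least 2-fold) and 2585 at day 7 (1348 at least 2-fold), and 207 were higher and 103 lower by at least 2-fold between the days. The nuclear respiratory chain list turned from -0.11 to 0.0103. Without day 3 graft 1 and day 7 graft 5 the counts between the days were 949 higher and 592 lower (644 and 366 at least 2-fold), and without control 4 as well 1548 and 1277 (841 and 537). With only the 10 samples compared 654 were lower between the days, 259 at least 2-fold. Camera with an estimated correlation ended the calls of the glycolysis list at day 3 (1.07, adjusted p = 0.419) and between the days (-0.68, adjusted p = 0.444). It ended those of the adipocyte list at day 3 (-2.51, adjusted p = 0.286), day 7 (-4.30, adjusted p = 0.258) and between the days (-1.52, adjusted p = 0.441). Fry ended 13 list calls between the days, that of the glycolysis list among them (-0.68, adjusted p = 0.0781). Leaving out each sample in turn gave 4464 to 5197 higher genes at day 3 (2567 to 2848 at least 2-fold) and 4471 to 5323 lower (2625 to 3106). At day 7 it gave 4779 to 5469 higher (2881 to 3132) and 4242 to 5156 lower (2463 to 2928), and between the days 228 to 943 higher (190 to 619) and 86 to 620 lower (60 to 292). The glycolysis median ranged over 0.94 to 1.19, 0.22 to 0.55 and -0.85 to -0.53 in the 3 comparisons, and the adipocyte median over -2.67 to -2.22, -4.55 to -4.04 and -1.84 to -1.28. Of the 784 genes called between the days, 784 were also called without control 4 and 738 without day 7 graft 5. The fewest, 317, were also called without day 7 graft 2. With the replicate number as a block (replicate block) 9725, 9724 and 659 genes were called in the 3 comparisons, 417 higher and 242 lower in the last, and the glycolysis medians were 1.06, 0.39 and -0.68. The block brought past the threshold the endothelial and fibroblast lists at day 7 (adjusted p = 0.0447 and 0.0391) and the B cell, resident macrophage, neutrophil and mesothelium lists between the days (0.0245, 0.036, 0.0437 and 0.0198). It ended the call of the skeletal muscle list at day 3 (0.124) and those of 5 named genes at day 3, with Ldha (0.0581) among them, 3 at day 7 and 5 between the days. Of 15 pairs of samples with the same number, 5 had correlated deviations above 0.1 (range -0.183 to 0.341). In 3 of the 15 pairs the same number was the best match among the 5 samples of the other group, as often as chance alone would give. A pairing by number was thus neither shown nor excluded, and the labels state none. The simulated recovery was 0% to 2.99% at 1.5-fold and 22.4% to 29.9% at 2-fold. Far fewer genes changed there than were called against the controls, so the adjustment set a stricter cutoff. At day 3, 9684 genes were called and 5449 of them changed at least 2-fold, so many calls were under 2-fold. At day 7 these were 9736 and 5525. The recovery thus does not measure what these 5 samples per group can show against the controls. Small changes can still be missed in all 3 comparisons.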

Other observations

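Further gene groups fell in the grafts, given for day 3 and then day 7 against the controls, with counts adjusted over the list alone in brackets where they differ. Of 8 thermogenic genes 7 fell at each day (medians -5.52 and -5.30, camera adjusted p = 0.000782 and 0.000563). With an estimated correlation the adjusted p = 0.286 and 0.258. Ucp1, the uncoupling protein of brown fat, went from 123 ± 121 to 0.254 ± 0.176 CPM at day 3 (-8.35 ± 1.84, adjusted p = 0.00127). Insulin signalling genes fell in 7 and 8 of 8 (medians -1.39 and -1.60, camera adjusted p = 0.000782 and 0.000146, adjusted p = 0.286 and 0.258 with an estimated correlation). Pentose phosphate genes fell in 5 and 6 of 7 [6 and 7] (medians -0.96 and -1.01, camera adjusted p = 0.0027 and 0.00105, adjusted p = 0.286 and 0.258 with an estimated correlation). The transketolase Tkt went from 1782 ± 822 to 195 ± 18.5 CPM at day 3. All 7 Schwann cell markers fell at both days (medians -1.73 and -1.91, camera adjusted p = 0.00187 and 0.00123, adjusted p = 0.286 and 0.258 with an estimated correlation). Dendritic cell markers fell in 6 of 7 at both days (medians -2.57 and -2.34, camera adjusted p = 0.00611 and 0.0102, adjusted p = 0.286 and 0.278 with an estimated correlation). Control 4, which also stood apart in the lymphocyte genes, had a mean log2 expression of 2.67 for them (other controls 3.67 to 4.34), and without it the day 3 median was -3.20.

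Other groups rose. Lysosomal genes rose in 13 and 12 of 13 (medians 1.28 and 1.41, camera adjusted p = 9.02e-06 and 1.00e-05, adjusted p = 0.286 and 0.278 with an estimated correlation). All 6 genes of angiogenic sprouting rose at both days (medians 4.10 and 4.32, camera adjusted p = 0.00393 and 0.0089, adjusted p = 0.286 and 0.308 with an estimated correlation). The tip cell peptide Apln went from 3.92 ± 1.59 to 280 ± 178 CPM at day 3. Interferon genes had 10 higher and 1 lower of 11 at day 3 (median 2.15, camera adjusted p = 0.000737, adjusted p = 0.37 with an estimated correlation). They had 5 and 1 at day 7 (median 0.63, camera adjusted p = 0.152), and that list passed without day 7 graft 5 (1.01, adjusted p = 0.0201), with no filter (0.0329) and with quality weights (0.0371). Immediate early and heat shock genes rose in 11 and 7 of 11 (medians 2.38 and 1.22, camera adjusted p = 4.05e-05 and 0.0171, adjusted p = 0.286 and 0.317 with an estimated correlation). NRF2 targets rose in 6 and 7 of 9 (medians 1.04 and 1.46, camera adjusted p = 0.0133 and 0.00372, adjusted p = 0.37 and 0.308 with an estimated correlation). The unfolded protein response had 7 higher and 1 lower, then 5 and 2, of 11 (medians 0.90 and 0.62, camera adjusted p = 0.0201 and 0.14). At day 3 its adjusted p = 0.37 with an estimated correlation, and at day 7 it passed with no filter (0.0185) and by fry (0.00233). Proliferation genes rose in 10 of 17 at day 3 (median 1.09, camera adjusted p = 0.0041, adjusted p = 0.574 with an estimated correlation). Acta2, smooth muscle actin, rose from 38.3 ± 11.4 to 85.4 ± 20.9 CPM at day 3 and 492 ± 189 at day 7. The pericyte and smooth muscle list had 1 higher and 2 lower, then 5 and 1, of 11 (camera adjusted p = 0.495 and 0.199), and passed at day 7 without day 7 graft 5 (1.05, adjusted p = 0.0387) and by fry (0.0301). Fibroblast markers rose in 4 and 7 of 9, with 1 lower at day 7 (camera adjusted p = 0.0988 and 0.0576). That list passed at day 3 without control 5 (0.83, adjusted p = 0.0467) or day 3 graft 3 (0.80, adjusted p = 0.0325), with no filter (0.0135) and by fry (0.00878). At day 7 it passed without control 4 or 5 (adjusted p = 0.0381 and 0.0254), day 3 graft 3 or 4 (0.0421 and 0.0483) or day 7 graft 3 (0.0449). There it also passed with median-of-ratios (0.0477) or upper-quartile scaling (0.0473), with no filter (0.0048), without the 50 most abundant genes (0.0484), with quality weights (0.0371) and by fry (0.000846).

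In lists with no camera call at either day, the higher and lower members were 1 and 5, then 2 and 5, of 9 for serine and glutamine metabolism (adjusted p = 0.279 and 0.152, and by fry 6.44e-05 and 1.92e-05). They were 4 and 2, then 4 and 3, of 9 for resident or alternatively activated macrophages (adjusted p = 0.463 and 0.75). For neutrophils they were 5 and 1, then 5 and 0 [4 and 0], of 10 (adjusted p = 0.332 and 0.14). The neutrophil list passed at day 3 with only the 10 samples compared (0.0437) and at day 7 with no filter (0.024) and by fry (0.0301). For mast cells they were 1 and 1, then 1 and 4, of 6 (adjusted p = 0.575 and 0.285). Glandular epithelium had 1 and 0 of 3 at both days (adjusted p = 0.481 and 0.511, and 0.0381 by fry at day 3). Its median of 0.29 at day 3 turned negative without control 1 or 4 (-0.12 and -0.10), day 3 graft 2, 3 or 4 (-0.30, -0.37 and -0.06) or day 7 graft 1, 3 or 4 (-0.06, -0.50 and -0.50). The filter then asks for fewer samples, so the tested members of this list can change, and these turns need not come from the library. Mesothelium had 0 and 2 [1 and 2], then 1 and 0, of 4 (adjusted p = 0.529 and 0.981). Erythroid genes had 3 and 0 [0 and 0], then 2 and 0 [0 and 0], of 6 (adjusted p = 0.315 and 0.285). Skeletal muscle genes had 3 of 12 lower [0] at day 3 (median -5.53, camera adjusted p = 0.0496, adjusted p = 0.629 with an estimated correlation). The mean log2 expression of the list in control 2 was 8.23 (other controls 1.83 to 4.96) and that in day 3 graft 1 was 4.60 (other day 3 grafts 0.422 to 0.727). The median was -6.28 without control 1, -4.58 without control 2 and -6.63 without day 3 graft 1. The call ended without control 4 or 5 (adjusted p = 0.117 and 0.0693), day 3 graft 1, 2, 3, 4 or 5 (0.057, 0.0969, 0.0702, 0.0771 and 0.079) or day 7 graft 2, 4 or 5 (0.0625, 0.0616 and 0.0598). It also ended with median-of-ratios (0.0534) or upper-quartile scaling (0.0838), with a filter at 1 CPM (0.0606), without the 50 most abundant genes (0.0508), with quality weights (0.276), without day 3 graft 1 and day 7 graft 5 together (0.0528) and by fry (0.0803). At day 7 1 of 12 [0] was lower (adjusted p = 0.0659), and the list passed without control 1 (-4.09, adjusted p = 0.0101) or day 7 graft 3 (-4.15, adjusted p = 0.042), with library totals (0.0353) and on TPM (0.00427).

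Between day 3 and day 7 some lists were lower by camera. These were fatty acid oxidation (adjusted p = 0.00221, and 0.708 with an estimated correlation), fatty acid and triglyceride synthesis (7.27e-05, and 0.577) and the unfolded protein response (0.0196, and 0.577). None of these 3 passed by fry (adjusted p = 0.43, 0.245 and 0.323). Insulin signalling was lower (adjusted p = 0.024, adjusted p = 0.577 with an estimated correlation), a call that ended without day 3 graft 2 or 5 (0.118 and 0.0552) or day 7 graft 5 (0.0581) and by fry (0.323). The nuclear respiratory chain was lower (adjusted p = 0.0196, adjusted p = 0.739 with an estimated correlation), a call that ended without day 3 graft 3 (0.103) or day 7 graft 4 (0.0997), on TPM (0.163) and by fry (0.632). The mitochondrial respiratory chain was lower (adjusted p = 0.0141, adjusted p = 0.708 with an estimated correlation), a call that ended without day 3 graft 2 or 5 (0.0804 and 0.0585) or day 7 graft 5 (0.0642), without the 50 most abundant genes (0.155) and by fry (0.452). Camera called no change for pentose phosphate, serine and glutamine, lysosome, fibroblast, skeletal muscle and Schwann cell genes (adjusted p = 0.389 each) or for the TCA cycle (0.105), thermogenic (0.238) and angiogenic genes (0.481). The TCA cycle list passed with only the 10 samples compared (0.0133) and the thermogenic list on TPM (0.0219). Camera also called no change for dendritic cell (adjusted p = 0.493), glandular (0.593) and erythroid genes (0.949). Single members were still called by limma, with 2 fibroblast genes higher and 1 lower (4 and 2 adjusted over the list alone). Another 1 lysosomal gene was called higher and 1 TCA cycle gene lower. Camera tests a shared direction, so members that go opposite ways can cancel. The glandular median of -0.16 was positive without any 1 library (0.16 to 1.67). Those fits asked for fewer samples in the filter and tested 16211 to 16584 genes. The tested members of lists tested only in part, such as this one and mesothelium, can therefore change with the fit, whichever library is left out. The erythroid median of 0.17 turned negative without day 3 graft 4 or 5 (-0.63 and -0.18) or day 7 graft 3 (-0.08), and the fibroblast median of 0.11 without day 3 graft 3 (-0.09). T and NK cell markers (median 0.99, adjusted p = 0.166) and B cell markers (median 1.25, adjusted p = 0.108) did not pass but passed without control 4 (adjusted p = 0.00394 and 0.000831). They also passed with only the 10 samples compared (adjusted p = 0.00635 and 0.000656) and with quality weights (0.0413 and 0.0477). The T and NK cell list passed without day 3 graft 1 and day 7 graft 5 together (adjusted p = 0.0292). With an estimated correlation both had an adjusted p = 0.739. Other lists that passed without 1 library were NRF2 targets (0.132, and 0.046 or 0.0451 without day 3 graft 4 or day 7 graft 2), neutrophils (0.231, and 0.048 without day 3 graft 4) and mast cells (0.166, and 0.0263 or 0.0402 without day 3 graft 3 or day 7 graft 5). So did resident macrophages (0.0669, and 0.0418, 0.046 or 0.00541 without control 5, day 3 graft 4 or day 7 graft 5) and mesothelium (0.0669, and 0.0249, 0.0161 or 0.0272 without day 7 graft 1, 3 or 4). Resident macrophages also passed with upper-quartile scaling (0.0478), library totals (0.0367), no filter (0.0289), quality weights (0.00701) and on TPM (0.0173). Mesothelium passed with no filter (0.00211) and NRF2 targets on TPM (0.049). The endothelial list had a median of 0.11 and a mean of 0.02 while camera pointed down (adjusted p = 0.925). Its median was -0.13 without day 3 graft 1 and -0.02 without day 7 graft 4.

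Fam177a met the naming rule for the largest rises but is uncertain, since it shares reads with the near-identical copy Fam177a2. It stood at 0 in all controls, and the sum of both copies was 40.6 to 55.8 CPM in controls, 53.6 to 56.8 CPM at day 3 and 43.4 to 49.1 CPM at day 7, so no fold is given.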
